A study of Mus musculus with 8 samples.

How the data were processed

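RNA from mpkCCDc14 cells was compared on 8 dual-colour arrays, 4 after 1 h and 4 after 6 h of aldosterone at 1 µM, each against ethanol vehicle of the same time. Per the labels, cDNA of treated cells was coupled to Cy5 and cDNA of control cells to Cy3 on every array, and the slides were read with a GenePix scanner. Array quality was, per the labels, examined on plots of ratio against intensity, by signal-to-noise ratio and by median intensity, with only arrays of adequate quality kept. The deposited values are log2 ratios of Cy5 over Cy3 that the authors normalized in R and Bioconductor, per the labels. The labels also name a one-class SAM test for choosing genes. The method of normalization, the background correction, the treatment of poor spots and whether repeat spots were averaged are not given in the sources used here, so the centring and scale within each array were taken as deposited. The column medians lay between -0.01 and 0.01. The direction of the ratio follows from the dyes in the labels, and all pairs of arrays correlated above 0 across features (r from 0.312 to 0.724). No pair of arrays had more than 2.08% of probes with equal values, so no array was taken for a repeat of another. Scanner intensities were not used here, so signal over background is unknown for each spot.

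The value table held 16361 probes. Values were present on all 4 arrays of a time or on none: 16083 probes had all 8 values, 202 had values at 1 h only and 76 at 6 h only. Probes were named through the platform annotation, in which 13768 had 1 gene symbol and 13 had several, and 2580 were not listed and remain unnamed here. Of these probes 13668 had an entrez identifier in a mouse gene table of assembly GRCm38.p6, which changed 0 symbols. Probes with the same single symbol were averaged, which joined probes for 938 genes. Features with values on at least 3 of 4 arrays per time were tested, in all 12535 genes and 2543 unnamed probes.

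Limma (version 3.58.1, in R 4.3.3) was fitted to the 8 arrays with a mean for each time, with 6 residual degrees of freedom per feature and empirical Bayes moderation (3.73 prior degrees of freedom). The means at 1 h and 6 h were tested against 0, and the difference of 6 h minus 1 h was tested in the same fit. P-values are two-sided and were adjusted over all features by the Benjamini-Hochberg method, with a threshold of 0.05. Lists were tested with camera on the moderated statistics at a preset correlation between genes of 0.01, adjusted over 17 lists. The lists, fixed before the data were examined, were corticosteroid early targets, sodium transport and its regulators, collecting duct principal cell markers, intercalated cell markers, other nephron segment markers, stromal, endothelial and blood cell markers, circadian clock, immediate early genes, NF-kB and inflammatory genes, cell cycle, cytosolic ribosomal proteins, oxidative phosphorylation, cholesterol synthesis, heat shock and unfolded protein response, extracellular matrix and TGF-beta response, epithelial junction and cytoskeleton, and vesicle traffic and ubiquitin. Members were matched by symbol or by a synonym in the gene table.

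Genes were named by a rule also fixed before the data were examined. It took, at each time, the 10 highest and 10 lowest mean ratios among genes with 1 symbol that passed the threshold with the same sign on every array. For the difference it took up to 5 genes in each direction that passed with no overlap between the arrays of the times, or, with none passing, the 5 with the smallest p. It added every measured corticosteroid early target and, for each other list, the 3 members with the smallest p at either time. Of the 105 genes so chosen 4 had several probes.

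The fit was tested on simulated data for 15078 features with the arrays' own spread, in which 67 features were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. At 1 h it recovered 65.7%, 91% and 100% of these, with 6.04% of calls false. At 6 h the figures were 70.1%, 97% and 100%, with 1.66% false, and for the difference 25.4%, 86.6% and 98.5%, with 2.1% false. No feature was called in any of the 3 comparisons when nothing was changed. The simulated noise was normal and independent between features, with no dye difference and few changed features. The real arrays differ in these points, so the false shares do not carry over to the counts below. The alternatives were other scalings between arrays, other filters, each probe by itself, robust moderation, array weights, each time fitted alone, one-class and 2-class SAM with all sign patterns or splits at a false discovery rate of 5%, list tests with an estimated correlation and with fry, and leaving out each array in turn. For a test at 1 h or at 6 h, only the 4 arrays of that time were left out in turn, though the fit shares its spread over all 8. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.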

Results

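Gene expression was measured in mpkCCDc14 cells, a mouse line derived from the kidney cortical collecting duct, the nephron segment in which aldosterone controls sodium reabsorption. Cells grown as epithelial layers on collagen-coated filters were kept in steroid-free serum and then received aldosterone, the adrenal mineralocorticoid hormone, at 1 µM, or its ethanol vehicle. RNA was taken after 1 h and after 6 h, with 4 dual-colour arrays for each time and 8 in all. On every array the aldosterone sample carried Cy5 and the vehicle sample Cy3, so a log2 ratio above 0 means a higher signal with aldosterone. The array medians lay between -0.01 and 0.01, and the standard deviation of the log2 ratios ranged from 0.306 on replicate 3 at 6 h to 0.583 on replicate 4 at 1 h. The dyes were never exchanged, so a gene-specific difference between the dyes is part of every ratio and of every test against a ratio of 1. The labels do not say whether arrays came from separate cultures, so the p-values measure the spread between these arrays, and 4 arrays per time limit the precision. Errors below are standard errors from the limma fit over all 8 arrays, with n = 4 at each time, and adjusted p-values are limma's after Benjamini-Hochberg adjustment over 15078 features.

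The comparison at 1 h addressed which transcripts had moved soon after the hormone was added. Some genes of sodium transport were above vehicle. Atp1b1, the beta-1 subunit of the sodium pump, had a log2 ratio of 0.84 ± 0.09 (adjusted p = 0.000914), and Scnn1a, the alpha subunit of the epithelial sodium channel, one of 0.42 ± 0.11 (adjusted p = 0.0124). Fkbp5, an immunophilin that binds steroid receptor complexes, stood at 0.53 ± 0.11 (adjusted p = 0.00562). Sgk1, the kinase that raises sodium channel activity, had a mean of 0.56 ± 0.35 (adjusted p = 0.227) and did not pass. Its arrays disagreed: replicates 1 and 2 gave 1.65 and 1.38, and replicates 3 and 4 gave -0.64 and -0.16. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, did the same, with 1.01 and 0.88 on replicates 1 and 2 and -0.60 and -0.15 on replicates 3 and 4. Its mean was 0.29 ± 0.23 (adjusted p = 0.344). Of 30 genes for sodium transport and its regulators, 9 were above vehicle, 3 below and 18 did not pass, with the same counts adjusted over the list alone. Over all 15078 features 41% were called at 1 h (3010 above and 3170 below), so such counts do not by themselves set a list apart. The list as a group did not pass (camera adjusted p = 0.0869, and 0.321 with an estimated correlation). It passed with fry, which tests a list against no change and not against other genes (adjusted p = 1.8e-05).

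Of the 28 measured genes in a list of corticosteroid early targets, 5 were above vehicle at 1 h, 5 were below and 18 did not pass, and the counts adjusted over the list alone were also 5 and 5. The share called over all features at 1 h was 41% (6180 of 15078). The 5 above were Fkbp5, Scnn1a, Cdkn1a, Cebpb and the metallothionein Mt2, which stood at 0.73 ± 0.17 (adjusted p = 0.00827). The 5 below were Cebpd, a transcription factor of the C/EBP family, at -0.56 ± 0.08 (adjusted p = 0.00172), Hif3a at -0.31 ± 0.07 (adjusted p = 0.00967; its probes gave -0.10 and -0.53), Zbtb16, Map3k6 and Per1. Per1, a clock gene, was at -0.28 ± 0.09 (adjusted p = 0.0332). As a group the list did not differ from other genes (median log2 ratio 0.10, camera adjusted p = 0.59). With an array left out the median ranged from 0.04 (without replicate 2, adjusted p = 0.977) to 0.16, and the lowest adjusted p was 0.0925 (without replicate 3). Mt2 stayed called without each 1 h array, but its ratio was 0.46 without replicate 4. Leaving out an array ended several of the other calls. Scnn1a was lost without replicate 1 (adjusted p = 0.0503) and Map3k6 without replicate 3 (0.0622). Zbtb16 was lost without replicate 3 (0.0611) or 4 (0.0741). Per1 was lost without replicate 1 (0.0625), 3 (0.144) or 4 (0.116). Cdkn1a was lost without replicate 1 (0.068), 2 (0.0666) or 4 (0.0613), and Cebpb without any given array (0.0535 to 0.133).

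Among genes for protein synthesis, respiration and epithelial structure, more passed above vehicle than below at 1 h. The dyes were never exchanged, so a dye difference and a response to aldosterone cannot be told apart in these lists. Of 55 cytosolic ribosomal protein genes, 37 were above vehicle, 2 below and 16 did not pass (45 above and 2 below adjusted over the list alone). Rplp0 was at 0.71 ± 0.10 (adjusted p = 0.00166) and Rpl39 at 0.83 ± 0.14 (adjusted p = 0.00277). Rpl13 went the other way, at -0.51 ± 0.15 (adjusted p = 0.0226), a call lost without replicate 1 (0.07), 2 (0.0775) or 3 (0.0504). The list's median ratio was 0.48 (camera adjusted p = 2.28e-08, but adjusted p = 0.391 with an estimated correlation). Replicate 4 stood apart from the other arrays, with a list median of 1.14 against 0.35, 0.20 and 0.22 on replicates 1 to 3, and without it the list's median ratio was 0.27. Of 51 oxidative phosphorylation genes, 23 were above vehicle and 2 below (24 and 2 adjusted over the list alone; camera adjusted p = 2.69e-05, but 0.321 with an estimated correlation). Ndufa1, a subunit of respiratory complex I, was at 0.45 ± 0.06 (adjusted p = 0.00134). The list of epithelial junction and cytoskeleton genes had 16 of 33 above vehicle and 2 below (19 and 2 adjusted over the list alone; camera adjusted p = 0.00101, but 0.321 with an estimated correlation). Among them were the tight-junction claudin Cldn8 at 0.59 ± 0.10 (adjusted p = 0.00263) and the actin cross-linker Flna at 0.53 ± 0.08 (adjusted p = 0.00226). Of 32 vesicle traffic and ubiquitin genes, 12 were above and 3 below, over all genes and adjusted over the list alone alike (camera adjusted p = 0.0078, but 0.333 with an estimated correlation). The retromer subunit Vps35 was at 0.57 ± 0.07 (adjusted p = 0.001). Of 26 heat shock and unfolded protein response genes, 12 were above and 2 below by either adjustment (camera adjusted p = 0.0106, but 0.321 with an estimated correlation). The chaperone Hspa5 was at 0.68 ± 0.10 (adjusted p = 0.00174) and the transcription factors Atf4 at 0.46 ± 0.08 (adjusted p = 0.00243) and Xbp1 at 0.46 ± 0.08 (adjusted p = 0.0025). Replicate 4 also stood apart in the lists of oxidative phosphorylation (list median 0.47, against 0.17 to 0.19 on the others), epithelial junction (0.44, against 0.11 to 0.18) and vesicle traffic (0.37, against 0.12 to 0.15). Without it the median ratios of these lists went from 0.25 to 0.15, from 0.21 to 0.15 and from 0.23 to 0.13, and each list still passed at the preset correlation. None of these 5 list calls held when the correlation between genes was estimated from the arrays. For the heat shock list the estimate was -0.016, below the preset 0.01, so correlation between genes does not account for that loss.

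The largest mean ratios at 1 h belonged to genes with no shared list. Tom1l1 was at -3.66 ± 0.30 (adjusted p = 0.000561), the prostaglandin D receptor gene Ptgdr2 at -3.15 ± 0.36 (adjusted p = 0.00092), the fibrinogen beta chain Fgb at -2.97 ± 0.24 (adjusted p = 0.000561). The cartilage collagen Col9a1 was at -2.54 ± 0.17 (adjusted p = 0.000377) and the pancreatic carboxypeptidase Cpa1 at -2.14 ± 0.12 (adjusted p = 0.000103). Gna13, Mucl2, Prom2, Abhd3 and Jchain had ratios between -2.52 and -1.76. In the other direction 4833417C18Rik reached 1.74 ± 0.42 (adjusted p = 0.0109), Proser1 1.71 ± 0.33 (adjusted p = 0.00432) and the sterol transporter Abcg5 1.22 ± 0.14 (adjusted p = 0.001). Cstf2, 2700046G09Rik, 4922502N22Rik, 1700034G24Rik, Btbd2, Zbtb14 and the parathyroid hormone gene Pth lay between 1.04 and 1.51. Each of these 20 genes was read by 1 probe whose signal over background is unknown. A dye difference is part of each ratio, so the sizes need not be changes in transcript. The calls of 5 of these 20 genes ended when an array was left out. Cstf2 was lost without replicate 1 (adjusted p = 0.062), 2 (0.0639) or 4 (0.0569), 4922502N22Rik without replicate 4 (0.052) and 1700034G24Rik without any given array (0.0539 to 0.194). Pth was lost without replicate 2 (0.133) or 3 (0.105), and Jchain without replicate 1 (0.0885), 2 (0.0639) or 4 (0.0536). Some sizes rest on 1 array. Without replicate 2 the ratio of Jchain was -0.71, of Cstf2 0.77 and of Pth 0.64. Without replicate 1 that of 4922502N22Rik was 0.64, and without replicate 4 that of 4833417C18Rik was 1.06.

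Over all 15078 features at 1 h, 6180 differed from a ratio of 1, with 3010 above vehicle and 3170 below. Most were small: 113 were also at least 2-fold, 19 above and 94 below. These counts hold any gene-specific dye difference as well as any response. Genes of families restricted to other tissues were called as often as the rest (76 of 185, 41.1%, against 41.3%), but less often above vehicle (7.57% against 21.1%) and more often below (33.5% against 20.2%).

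At 6 h several known corticosteroid targets and sodium transport genes were above vehicle. Fkbp5 reached a log2 ratio of 2.10 ± 0.11, or 4.28-fold (adjusted p = 6.62e-05), with 2.07 to 2.13 on the 4 arrays. Sgk1 was at 1.91 ± 0.35 (3.76-fold, adjusted p = 0.00794) and was above 0 on all 4 arrays, from 1.46 to 2.65. Scnn1a was at 1.47 ± 0.11 (2.78-fold, adjusted p = 0.000201), Atp1b1 at 1.35 ± 0.09 (2.54-fold, adjusted p = 0.000201). Tsc22d3 was at 1.27 ± 0.23 (2.41-fold, adjusted p = 0.00778) and Usp2, a ubiquitin protease, at 1.05 ± 0.15 (2.06-fold, adjusted p = 0.0033). Sult1d1, a cytosolic sulfotransferase, was at 2.34 ± 0.15, or 5.05-fold (adjusted p = 0.000156). The calls of these 7 genes at 6 h held without each of the 4 arrays at 6 h in turn.

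Of the 28 corticosteroid early targets, 9 were above vehicle at 6 h, 1 was below and 18 did not pass (9 and 2 adjusted over the list alone). Besides the genes above, Cebpb was at 0.51 ± 0.08 (adjusted p = 0.00388), Cdkn1a at 0.37 ± 0.08 (adjusted p = 0.0123). Cdkn1c was at 0.58 ± 0.15 (adjusted p = 0.0261) and Gadd45g at 0.46 ± 0.10 (adjusted p = 0.0163). Hif3a was below vehicle at -0.31 ± 0.07 (adjusted p = 0.0224), the mean of probes at -0.10, which did not pass by itself, and -0.51. Per1 did not pass at -0.08 ± 0.09 (adjusted p = 0.554), nor did Zbtb16 at 0.00 ± 0.13 (adjusted p = 0.991), Klf9, Klf15, Dusp1, Errfi1, Edn1, Ddit4 or Nfkbia. The list's median was 0.22 (camera adjusted p = 4.75e-06, but adjusted p = 0.315 with an estimated correlation). With an array left out some of these calls ended. Cdkn1a was lost without replicate 2 (adjusted p = 0.056), Cdkn1c without replicate 3 (0.089) or 4 (0.11). Gadd45g was lost without replicate 1 (0.0581) or 3 (0.0668), and Hif3a without replicate 1 (0.0611), 2 (0.0867) or 4 (0.0917). The ratios themselves were then 0.34 for Cdkn1a, 0.54 and 0.43 for Cdkn1c, 0.42 in both cases for Gadd45g, and from -0.31 to -0.28 for Hif3a.

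Of 30 genes for sodium transport and its regulators, 8 were above vehicle at 6 h and none below (10 above and 1 below adjusted over the list alone), and the list's camera adjusted p was 0.000773, but 0.129 with an estimated correlation. It shares Scnn1a, Sgk1, Tsc22d3 and Usp2 with the corticosteroid list, and without these 4 genes its adjusted p was 0.0773. Its estimated correlation was -0.027, below the preset 0.01, so correlation between genes does not account for the 0.129. Among principal cell markers, 5 of 22 were above and 2 below, and as many adjusted over the list alone (camera adjusted p = 0.0638, and 0.0428 without replicate 4). The potassium channel Kcnk1 was at 0.62 ± 0.09 (adjusted p = 0.00312). The transcription factor Elf5 was at -1.40 ± 0.18 (adjusted p = 0.00224) after -1.12 ± 0.18 at 1 h (adjusted p = 0.00226).

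**Figure D1:**
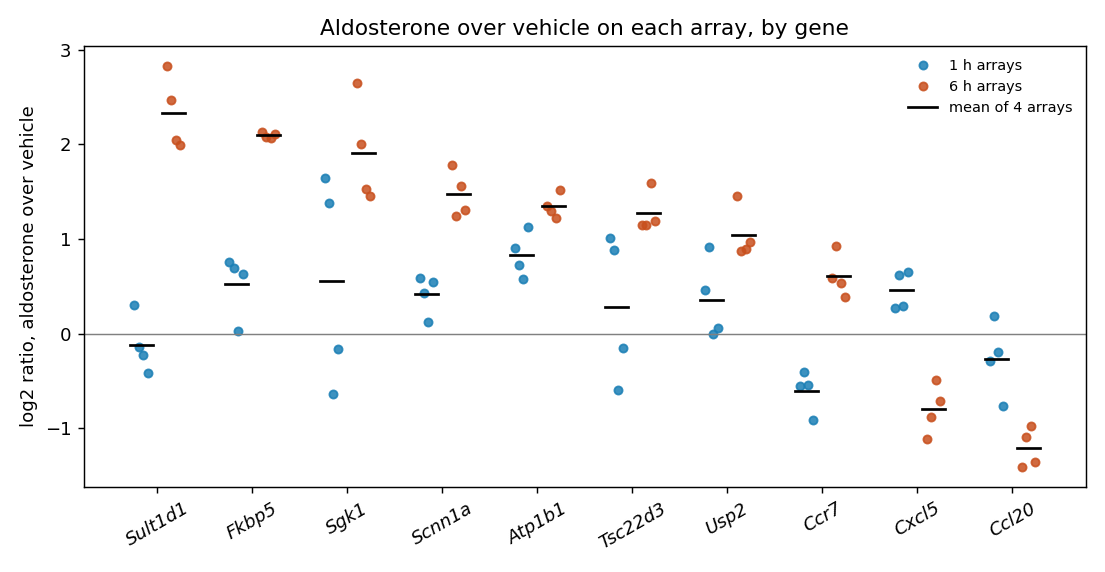
Log2 ratio of aldosterone over vehicle (vertical axis) for 10 genes (horizontal axis), with a point for each array at 1 h (blue) and 6 h (orange) and a bar at the mean of 4 arrays. Fkbp5 lies between 2.07 and 2.13 on the 6 h arrays, and Sgk1 at 1 h lies at 1.65 and 1.38 on replicates 1 and 2 and at -0.64 and -0.16 on replicates 3 and 4.

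Chemokine genes were among those below vehicle at 6 h. Ccl3, a macrophage-attracting chemokine, was at -2.67 ± 0.35 (adjusted p = 0.00224). Ccl20, which attracts lymphocytes and dendritic cells, was at -1.21 ± 0.14 (adjusted p = 0.00133) and Cxcl5, which attracts neutrophils, at -0.80 ± 0.11 (adjusted p = 0.00258). The signal over background is unknown for these genes and a dye difference is part of each ratio. Calls below vehicle at 6 h were also more frequent among genes restricted to other tissues (24.3%) than among other named genes (9.77%). Of 30 NF-kB and inflammatory genes, 5 were below vehicle and 2 above (6 and 2 adjusted over the list alone), and the list as a group did not pass (median -0.07, camera adjusted p = 0.0978). It passed without replicate 3 (adjusted p = 0.0483), and its median was -0.12 without replicate 2. Rela, the NF-kB subunit p65, was above vehicle at 0.23 ± 0.06 (adjusted p = 0.0347), a call lost without any given array (adjusted p from 0.0816 to 0.123).

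Another 6 lists passed at 6 h at the preset correlation, with ratios above those of other genes, and none with an estimated correlation (adjusted p from 0.129 to 0.671). They were oxidative phosphorylation (7 of 51 above, none below; camera adjusted p = 0.000773), vesicle traffic and ubiquitin (8 of 32 above, 2 below; 0.00751) and heat shock and unfolded protein response (3 of 26 above, none below; 0.0143). The others were epithelial junction and cytoskeleton (4 of 33 above, 1 below; 0.0204), cytosolic ribosomal proteins (6 of 55 above, 2 below; 0.0229) and cholesterol synthesis (1 of 17 above, none below; 0.0229). Adjusted over the list alone, the numbers above vehicle were 7, 10, 3, 4, 5 and 1. Over all 15078 features 17.8% were called at 6 h (1075 above and 1610 below). Vps35 was at 0.48 ± 0.07 (adjusted p = 0.00312) and Ndufb8, a complex I subunit, at 0.46 ± 0.07 (adjusted p = 0.00456). Rpl13 was below vehicle at -1.02 ± 0.15 (adjusted p = 0.00347), against the direction of its list. With an estimated correlation none of these 6 passed (adjusted p = 0.315, 0.315, 0.129, 0.369, 0.671 and 0.129 in that order). The estimate was below the preset 0.01 for heat shock (-0.016) and cholesterol synthesis (-0.026), so correlation between genes does not account for those losses. As at 1 h, a dye difference and a response to aldosterone cannot be told apart in these lists. The cholesterol synthesis call ended without replicate 1 at 6 h (adjusted p = 0.0504), and the ribosomal call without replicate 3 (0.0704) or 4 (0.0666).

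Other genes with large ratios at 6 h were 1700034G24Rik at 2.35 ± 0.46 (adjusted p = 0.0102), Cstf2 at 2.30 ± 0.47 (adjusted p = 0.0121) and C2cd4b at 2.24 ± 0.42 (adjusted p = 0.00824). Cfp, which encodes the complement regulator properdin, was at 2.00 ± 0.26 (adjusted p = 0.00224), and the tight-junction protein gene Marveld3 at 1.76 ± 0.28 (adjusted p = 0.00456). The clathrin light chain Clta was at 1.70 ± 0.40 (adjusted p = 0.0209) and the mucin Muc16 at 1.67 ± 0.31 (adjusted p = 0.00837). Below vehicle, Spock3, Dydc1, Ccdc81, Clec12b, Fgb, Ptgdr2, Rec114, 4930509J09Rik and Arhgap20 lay between -2.47 and -1.84. As at 1 h, the signal over background is unknown for these genes and a dye difference is part of each ratio. Cstf2 was lost without replicate 4 (adjusted p = 0.0573), Clta without replicate 1 (0.0524), 2 (0.069) or 4 (0.0885), and Clec12b without replicate 1 (0.0786) or 3 (0.0556). Without replicate 3 the ratio of Clec12b was -1.42, and without replicate 2 that of Spock3 was -1.61.

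At 6 h 2685 of 15078 features differed from a ratio of 1, with 1075 above vehicle and 1610 below, and 164 were also at least 2-fold, 41 above and 123 below. The number of features changed at 6 h depends on the arrays and their scaling. It fell to between 1099 and 1746 when any 1 array at 6 h was left out, and rose to 5007 when the arrays were centred and scaled to a common spread. Among genes restricted to other tissues 2 of 185 were above vehicle (1.08%, against 7.64% of other named genes) and 45 below (24.3% against 9.77%).

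Most features called at 6 h were called in the same direction at 1 h (67.9%). Of 15078 features 778 were above vehicle at both times and 1046 below at both, against 215 and 338 for independent lists. Another 3 were called in each of the 2 opposite orders, against 321 and 226. Both times were tested with the same estimate of spread for a feature, so their calls are not independent and the numbers for independent lists are only a rough guide. The correlation of the mean log2 ratios at the 2 times was 0.677 across features, which are not independent replicates. Among the genes with large ratios at both times were Fgb, Ptgdr2, Elf5, Tom1l1 (-1.79 ± 0.30 at 6 h, adjusted p = 0.00596) and Abcg5 (1.06 ± 0.14 at 6 h, adjusted p = 0.00259). A dye difference that is the same at both times would add to this overlap, and the arrays do not separate the sources.

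**Figure D2:**
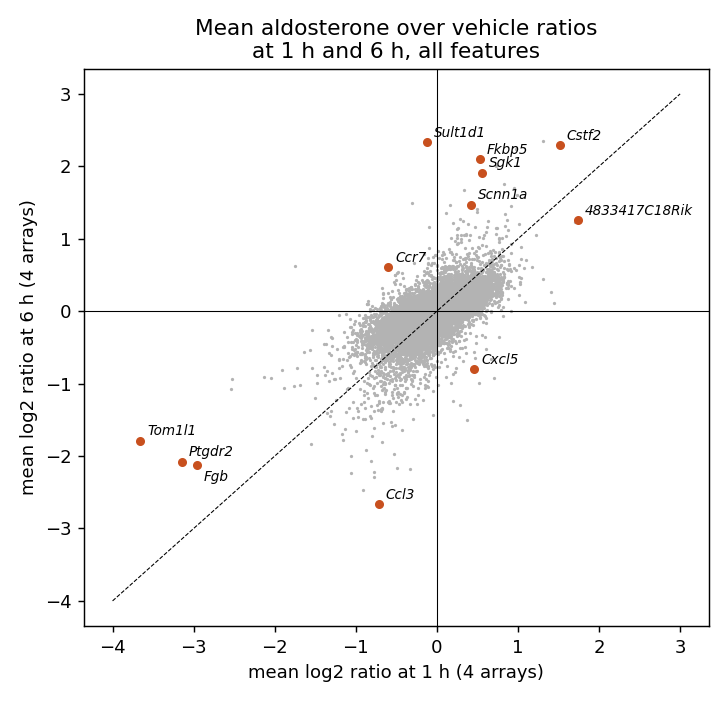
Mean log2 ratio of aldosterone over vehicle at 1 h (horizontal axis) against that at 6 h (vertical axis) for 15078 features, with 4 arrays per time; the dashed line marks equal ratios and 12 genes are named. Most features lie along the diagonal (r = 0.677), and Sult1d1, Fkbp5, Sgk1 and Scnn1a lie above it.

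The difference between the times, in which a constant dye difference cancels, asked which ratios changed from 1 h to 6 h. Sult1d1 rose by 2.46 ± 0.21 on the log2 scale, from -0.12 to 2.34 (adjusted p = 0.00725, n = 4 arrays per time), and Fkbp5 by 1.57 ± 0.15, from 0.53 to 2.10 (adjusted p = 0.0122). The chemokine receptor Ccr7 went from below vehicle at 1 h (-0.61 ± 0.10) to above it at 6 h (0.61 ± 0.10), a difference of 1.22 ± 0.15 (adjusted p = 0.0426). Cxcl5 went the other way, from 0.46 ± 0.11 to -0.80 ± 0.11, a difference of -1.26 ± 0.15 (adjusted p = 0.0426). For each of these 4 genes no array at 6 h overlapped an array at 1 h. Scnn1a differed by 1.05 ± 0.15 and did not pass (adjusted p = 0.0798), nor did Sgk1 (1.35 ± 0.50, adjusted p = 0.256), Tsc22d3 (0.99 ± 0.33, adjusted p = 0.233), Usp2 (0.69 ± 0.21, adjusted p = 0.213) or Atp1b1 (0.51 ± 0.13, adjusted p = 0.202).

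Across the 28 corticosteroid early targets the ratios were higher at 6 h than at 1 h, with a median difference of 0.18 and 23 genes above 0 (1 gene passing, 2 adjusted over the list alone; camera adjusted p = 1.24e-05, but 0.601 with an estimated correlation). The medians on the 1 h arrays were 0.28, 0.27, -0.10 and -0.14, and on the 6 h arrays 0.28, 0.30, 0.15 and 0.27, so replicates 1 and 2 at 1 h stood at the level of the 6 h arrays. The median difference was 0.11 without replicate 3 at 1 h, and 0.31 without replicate 2 at 1 h. The NF-kB and inflammatory genes were lower at 6 h, with a median difference of -0.15 and 22 of 30 genes at or below 0 (1 passing, 2 adjusted over the list alone; camera adjusted p = 0.00724, but 0.601 with an estimated correlation). Their median was -0.09 without replicate 4 at 1 h. The 55 ribosomal protein genes were also lower at 6 h, with a median difference of -0.32 and none passing singly or adjusted over the list alone. The camera adjusted p was 3.09e-07, but 0.601 with an estimated correlation. The median difference was -0.12 without replicate 4 at 1 h, -0.16 with centring and scaling and -0.20 with quantile normalization. With fry the corticosteroid, NF-kB and ribosomal lists did not pass (adjusted p = 0.129, 0.072 and 0.258).

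**Figure D3:**
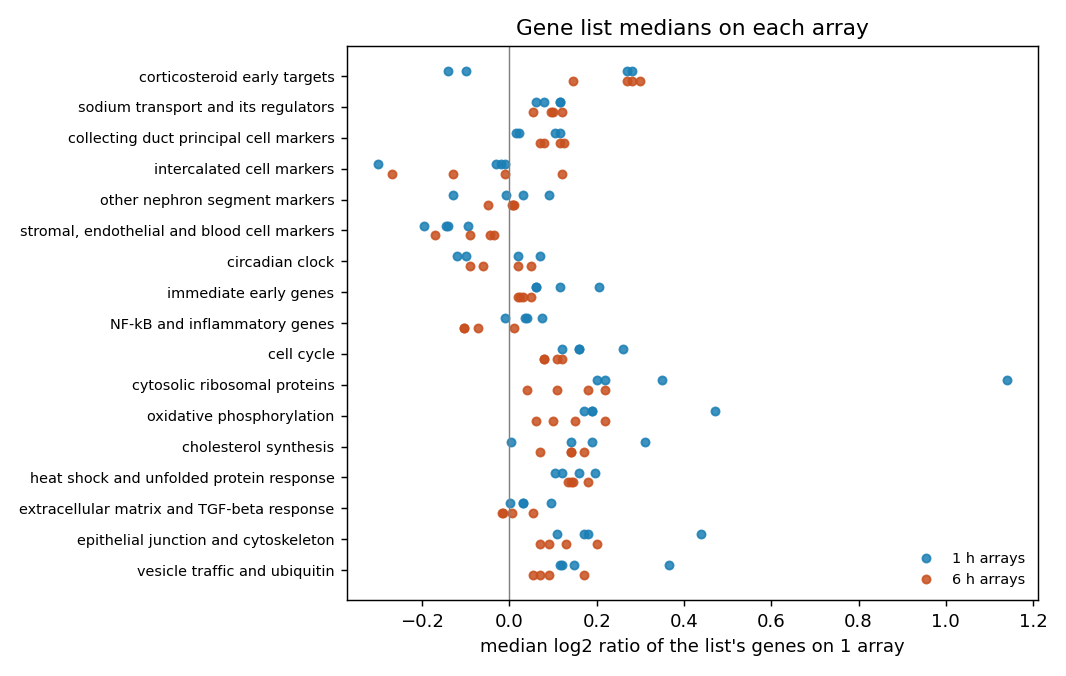
Median log2 ratio of aldosterone over vehicle over the genes of each list (horizontal axis) on each array, for 17 gene lists (vertical axis), with 4 arrays at 1 h (blue) and 4 at 6 h (orange). The ribosomal list lies at 1.14 on replicate 4 at 1 h and between 0.04 and 0.35 on the other 7 arrays, and the corticosteroid list at 1 h lies at 0.28, 0.27, -0.10 and -0.14.

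In all, 4 of 15078 features differed between the times, 3 higher and 1 lower at 6 h, with 2429 at an unadjusted p under 0.05 where 754 are expected by chance. The number of features differing between 6 h and 1 h rests on the test and the set of arrays. It was 9 with centring and scaling, 11 with quantile normalization, 8 with array weights and 288 with 2-class SAM (273 higher and 15 lower at 6 h). With an array left out it was 2 without replicate 1 or replicate 2 at 1 h, 0 without replicate 4 at 1 h, 1 without replicate 1 or replicate 3 at 6 h and 0 without replicate 2 at 6 h. It was 3 without replicate 3 at 1 h and 5 without replicate 4 at 6 h. The log2 differences kept their sizes, with Sult1d1 between 2.29 and 2.60 and Fkbp5 between 1.40 and 1.65. Sult1d1 was lost without replicate 4 at 1 h (adjusted p = 0.0575) or replicate 2 at 6 h (0.0538). Fkbp5 was lost without replicate 4 at 1 h (0.0667) or replicate 1 (0.0765), 2 (0.0764) or 3 (0.053) at 6 h. Ccr7 was lost without any array other than replicate 4 at 6 h (0.0844 to 0.143) and Cxcl5 without any given array (0.053 to 0.15).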

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

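The tests on tissue-restricted families, on the array behind the ribosomal list and on the array behind the corticosteroid list were chosen after results of the same arrays had been seen; the tests on other groupings of the arrays were set beforehand.

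A first pattern is the very large number of features that differed from a ratio of 1, with 6180 at 1 h and 2685 at 6 h. If the aldosterone response were the whole of it, genes of 15 families restricted to other tissues, such as olfactory receptors, hair keratin-associated proteins and lens crystallins, should be called much less often than other genes. They were called at 0.994 times the share of other named genes at 1 h (95% interval 0.836 to 1.18) and at 1.46 times at 6 h (1.14 to 1.87). Without the 3 families that hold genes already seen among the most changed, the ratios were 0.955 and 1.49. The families were picked by gene name, and whether their members are expressed in these cells was not examined. If they are not expressed, the ratios argue against a hormone response as the whole cause. A dye or background deviation that needs no expression of the gene could then give such calls. The calls in these families went mainly downward, with ratios of 1.66 for calls below vehicle at 1 h and 2.49 at 6 h. For calls above vehicle the ratios were 0.358 (0.216 to 0.593) and 0.142 (0.0356 to 0.563). Both intervals lie below the 0.75 that such a deviation was taken to need, but this bound was set after these ratios were seen. It replaced a lower bound, which the upper limits at both times exceed. The test therefore does not decide whether such a deviation is the whole cause of the higher calls. Dye bias of expressed genes and the response to aldosterone cannot be told apart within a time, because the dyes were never exchanged; of the 8 sign patterns of the 4 arrays only the real one gave as many features at either time (value 1, highest other 0), but 8 patterns are too few for a share under 0.05.

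A second pattern is the difference between the times, led by Sult1d1 (2.46), Fkbp5 (1.57), Ccr7 (1.22) and Cxcl5 (-1.26), each of which differed in the test of the difference itself. Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave as many as 4 features (value 1, highest other 0). A share of 1 in 35 is the smallest this test can reach, so it argues against chance for this count but does not exclude it. The count also depended on single arrays. It ranged from 0 to 5 with an array left out, and each of the 4 genes lost its call without some array. The corticosteroid early targets differed as a list, with a median of 0.18, but not with an estimated correlation (adjusted p = 0.601). Leaving out replicate 3 at 1 h lowered that median to 0.114, so a part played by 1 array can be neither shown nor excluded, and the list stood at 0.28 and 0.27 on replicates 1 and 2 at 1 h, as high as at 6 h, against -0.10 and -0.14 on replicates 3 and 4. A constant dye bias cancels in this difference, while an unlabelled difference among the 1 h arrays and a slower build-up of the response to aldosterone both remain open and untested.

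Another pattern is the ribosomal protein list, which was lower at 6 h than at 1 h, with a median difference of -0.32. On replicate 4 at 1 h, the array with the widest ratios, the list's median was 1.14. Without that array the median difference was -0.1175, so most of it may come from that array; the list test still passed (adjusted p = 0.000318), though with an estimated correlation the list does not pass on all 8 arrays (adjusted p = 0.601). Whether the array differed in labelling, scanning or culture was not tested, and a true fall between the times remains open for the rest.

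The NF-kB and inflammatory list also differed between the times, with a median of -0.15, but not with an estimated correlation (adjusted p = 0.601). Without replicate 4 at 1 h it was -0.0854, and the list still passed at the preset correlation (camera adjusted p = 0.00648). This array was picked out after the result was seen, and whether the difference rests on 1 array was not tested for this list.

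In 14 of 178 sets of 4 arrays examined for the named genes, 1 array stood far from the other 3. Chance alone gives this in about 1 in 20 sets. Replicate 4 at 1 h or at 6 h was the array apart in 5 of them. The same replicate number at the 2 times does not mark a matched array. At 1 h it gave 3.75 for 4833417C18Rik (others 0.83 to 1.20), -3.04 for Mucl2 (others -1.59 to -1.48) and 1.04 for Stard4 (others 0.30 to 0.41). At 6 h it gave -3.06 for Fgb (others -1.91 to -1.72) and 0.59 for Ndufb8 (others 0.40 to 0.42). Replicate 3 stood apart for Tsc22d3 at 6 h with 1.59 (others 1.15 to 1.19), and for Cdkn1a at 1 h with 0.01 (others 0.35 to 0.38). It also did so for Rela at 6 h, with 0.28 (others all 0.21). Replicate 2 at 6 h gave -2.50 for Arhgap20 (others -1.67 to -1.53) and 0.34 for Ndufa1 (others all 0.32). Replicate 1 gave -0.25 for Map3k6 (others -0.09 to -0.06), -0.29 for Gadd45b (others -0.07 to -0.04) and 0.13 for Jund (others 0.28 to 0.31) at 6 h, and 0.18 for Pdk4 at 1 h (others -0.04 to -0.02).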

How the results depend on the processing

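The settings without the widest array of each time, with a size of at least 1 or with an adjusted p under 0.1 were chosen after seeing the data. For features changed at 1 h, the 6180 stayed within 1.5 times when scaling, filters, moderation or test differed, from 4893 with only that time's arrays to 7991 with one-class SAM. Of them 113 were also at least 1 in size. For features changed at 6 h, the 2685 became 5007 with centring and scaling, 4863 with quantile normalization, 4042 with array weights and 5112 with one-class SAM. Of the 2685, 164 were at least 1 in size. Of the 5007 and 4863, the features shared with the 2685 numbered 2685 and 2680. For features differing between 6 h and 1 h, the 4 became 9 with centring and scaling, 11 with quantile normalization, 8 with array weights, 288 with 2-class SAM (273 higher at 6 h) and 8 at an adjusted p under 0.1. Leaving out each array of the time tested in turn gave 4327 to 5211 features at 1 h and 1099 to 1746 at 6 h. Between the times, leaving out each of the 8 arrays gave 0 to 5. Without the widest array of each time the counts were 5085, 2387 and 3. The 2 filters on missing values removed no tested feature and so tested nothing. The lists called were 5, 8 and 3 at 1 h, at 6 h and between the times. With an estimated correlation they were 0, 0 and 0. That setting also raised the unadjusted camera p of some lists whose estimate was below 0.01 (heat shock at 6 h, from 0.0042 to 0.0142). The lost calls therefore do not measure correlation between genes alone. Fry, which tests a list against no change and not against other genes, called 12, 8 and 0. At 6 h its lists were not the same 8. It did not call the ribosomal (adjusted p = 0.431) or epithelial junction list (0.0688). It called principal cell markers (0.00599) and NF-kB genes (0.0141) instead. With camera at the preset correlation, leaving out each array gave 5 to 5, 7 to 8 and 3 to 5. Each of the 16 list calls kept its direction under every scaling. Of the named genes called, 14 of 66 at 1 h, 18 of 52 at 6 h and 4 of 4 between the times lost the call without some array, and none changed sign. For Birc3 at 6 h, which did not pass (0.03), 1 of its probes alone was reversed, at -0.39 (adjusted p = 0.0141). Its other probe was at 0.44, so the mean of 0.03 joins probes of opposite sign and describes neither. The cause of each change was not tested, except that fewer arrays leave fewer degrees of freedom. No paired analysis was possible because the labels number only 2 of the 8 arrays, so arrays of the times cannot be matched. Signal over background was not used here, so what it limits is unknown.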

Other observations

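Cell cycle genes were mixed at 1 h: of 37 measured, 17 were above vehicle and 6 below (19 and 8 adjusted over the list alone; camera adjusted p = 0.121). Ccna2, the cyclin of S phase and G2, was at 0.78 ± 0.11 (SE, n = 4; adjusted p = 0.00135) and the centromeric histone Cenpa at 0.53 ± 0.08 (adjusted p = 0.00194), while the D-type cyclin Ccnd2 was at -0.66 ± 0.09 (adjusted p = 0.00134). At 6 h 2 were above and 2 below (camera adjusted p = 0.154, and 0.047 without replicate 4 of both times, a setting chosen after seeing the data). Of 36 immediate early genes, 7 were above and 3 below at 1 h (3 and 2 adjusted over the list alone; camera adjusted p = 0.206), with Jund at 0.71 ± 0.12 (adjusted p = 0.00279) and Gadd45b at -0.42 ± 0.07 (adjusted p = 0.00224). Dusp6, a phosphatase that acts on ERK, was at 0.86 ± 0.19 at 6 h (adjusted p = 0.0158), lost without replicate 1 (0.0536), 2 (0.0516) or 4 (0.0666). Of 17 cholesterol synthesis genes, 6 were above and 1 below at 1 h by either adjustment (camera adjusted p = 0.164), with the regulator Srebf2 at 0.34 ± 0.07 (adjusted p = 0.00451). Of 32 extracellular matrix and TGF-beta response genes, 9 were above and 5 below at 1 h (10 and 8 adjusted over the list alone; camera adjusted p = 0.521), with the laminin chain Lama5 at 0.63 ± 0.10 (adjusted p = 0.00202) and the collagen Col1a1 at -0.65 ± 0.10 (adjusted p = 0.00231); the list's median was 0.005, -0.01 after centring and scaling, and from -0.01 to 0.05 with an array left out.

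Markers of other cell types were also among the calls. Over all 15078 features 41% were called at 1 h and 17.8% at 6 h. Of 13 intercalated cell markers, 2 were above and 5 below at 1 h by either adjustment (camera adjusted p = 0.521), with Dmrt2 at -0.61 ± 0.12 (adjusted p = 0.00511) and the carbonic anhydrase Car12 at -0.47 ± 0.11 (adjusted p = 0.0106). Of 15 markers of other nephron segments, 2 were above and 2 below at 1 h and none passed at 6 h (camera adjusted p = 0.954 and 0.807). Of 16 stromal, endothelial and blood cell markers, 1 was above and 5 below at 1 h (camera adjusted p = 0.164), with Col1a1 among those below and the T-cell gene Cd3e above, at 0.47 ± 0.10 (adjusted p = 0.00558). Of 17 circadian clock genes, 1 was above and 3 below at 1 h (1 and 1 adjusted over the list alone; camera adjusted p = 0.75), with Bhlhe41 at 0.33 ± 0.08 (adjusted p = 0.0122) and Nr1d1 at -0.39 ± 0.11 (adjusted p = 0.0204; 0.0508 without replicate 3, and a ratio of -0.23 without replicate 4). At 1 h 9 of 30 sodium transport genes were above vehicle and 3 below (camera adjusted p = 0.0869), and 7 of 22 principal cell markers above and 4 below (camera adjusted p = 0.336).

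Other genes split the 1 h arrays as Sgk1 did; they were picked after their values were seen. Ccn2, a matricellular growth factor gene, gave 1.35, 1.26, -0.57 and 0.01 on replicates 1 to 4 at 1 h and 0.55 to 1.06 at 6 h. Dusp6 gave 0.91, 0.37, -0.14 and -0.53 at 1 h, and Dusp1 0.29, 0.63, -0.59 and -0.31. Atp1b1 did not split in this way, with 0.90, 0.73, 0.58 and 1.13. Another 3 genes came close in the test between the times: Rpl3l, a muscle ribosomal protein gene, differed by 1.79 ± 0.23 (adjusted p = 0.0531), Cpa1 by 1.22 ± 0.16 (adjusted p = 0.0629) and Serinc3 by 0.91 ± 0.13 (adjusted p = 0.0696). The 202 probes with values at 1 h only and the 76 at 6 h only enter no comparison.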
